A study of Mus musculus with 3 samples.

How the data were processed

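RNA of sorted mouse CD8+ T cells was measured on 3 Affymetrix mouse 430 2.0 arrays, 1 for each of 3 groups. The groups were NK1.1+ cells and NK1.1− cells of mice that lack the type II TGF-β receptor in T cells (KO), and cells of littermates heterozygous for the floxed receptor gene (control). Groups were taken from the sample titles. The title of the control array calls its cells NK1.1−, and so does the end of the design text, while an earlier passage of the same text describes unfractionated CD8+ cells, so the gate of the control is not settled.

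The values in the deposited table are probe set intensity values on a linear scale, from 2.6 to 55467.7 among probe sets other than controls. The submitters' processing notes name GCRMA, version 1.1.3, a method that subtracts background by probe sequence, normalizes arrays and combines the probes of a set; its settings are not given in the sources used here. The design of the comparisons had foreseen values on the log2 scale or linear ones, and log2 was taken of the deposited intensity after raising values under 1 to 1, which applied to no value. All 3 columns belonged to a sample.

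The table holds 45101 probe sets, of which 64 are array controls. GEO's platform annotation, as given with the values, names, among the 45037 other probe sets, exactly 1 gene symbol for 34945, several for 932 and none for 9160. Entrez identifiers of 34741 of the single-symbol probe sets matched a RefSeq gene table of assembly GRCm38.p6, which changed 0 symbols. That table was used for names only, and no coordinates are given because the build behind the probe sets is not given in the sources used here. Probe sets with several symbols or none were named for no gene. A gene's value was that of its single-symbol probe set with the highest mean over the 3 arrays, which gave 18193 genes.

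A value counted as measured at or above a level of 10.3, or 3.37 on the log2 scale, which is the 95th percentile over the 3 arrays of 144 probe sets of olfactory, vomeronasal and taste receptors, keratin-associated proteins and lens crystallins. Values below the level were raised to it before differences were taken, so that a difference with its lower side at the level is a lower bound and is written "at least". A gene was called higher or lower where this log2 difference was at least 1 (2-fold). With 1 array per group there is no spread between mice, so no test was made and no p-value is given, and the number of arrays limits the precision. Leaving out a replicate was not possible.

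The rule for named genes was fixed before the data were examined, as were the comparisons and all gene lists except the 3 described in the closing section. Per comparison it took, among genes with an established symbol whose measured probe sets all differed in the same direction, the 8 with the largest differences each way among genes measured on both arrays, and the 5 each way among genes measured on the brighter array only. It also took 2 to 4 members per gene list with the largest absolute difference, and Tgfbr2 and the NK1.1 gene Klrb1c always. The 33 gene lists held 659 member names, of which 576 matched a gene on the array; the lists cover NK cell receptors and adaptors, effector, naive, activation, cytokine, chemokine, homing and inhibitory genes, cytokine and TGF-β signalling, proliferation, interferon response, T cell lineage, innate-like, regulatory and thymocyte genes, apoptosis, metabolism, ribosomal and immediate early genes, markers of 7 groups of other cell types, sex-linked genes and housekeeping genes. A list is described by how many of its measured members were called and by the percentile of its median log2 difference among 10000 random lists of the same size matched on mean value in 10 classes (seed 1). Such a percentile describes these arrays and is no p-value. In any list, a member below the level on the second-named array of a comparison could not be called lower. One below the level on the first-named array could not be called higher. Some genes stand in more than 1 list, such as Itgae, Skil and Ccr7.

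Calls shared by both KO subsets were set beside the overlap of independent lists and beside 100 simulated sets of 3 unchanged arrays, whose noise in each of 10 classes of mean value was taken from the differences between the NK1.1− KO and control arrays. Those differences also hold effects of the genotype, so the simulated noise is not pure measurement noise. The rules were tested on simulated data of 18193 genes with known changes. The genes changed by a known fold were all bright, with a mean at least 3 above the level on the log2 scale. How often such changes are called in dimmer genes was not examined. For NK1.1− KO against control, 62 of 71 genes changed 3-fold and 66 of 66 changed 6-fold were called, with 10 of 63 changed 1.5-fold, 0 in the wrong direction, and 6.6% of 9769 measured unchanged genes. A list of 30 genes raised by 1 on the log2 scale reached the percentile 100 in each of the 3 simulated comparisons. Unchanged lists of 30 genes lay at 42.5, 15.0 and 1.57. A list was taken to stand apart from matched random lists below the percentile 2.5 or above 97.5. By that bound the unchanged list at 1.57 would wrongly have stood apart.

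Alternatives were median centring, quantile normalization and cyclic loess of the 3 arrays, a level at the median or at the 75th percentile of all values, no level, an offset of 32 on the linear scale without a level, the mean of all probe sets of a gene, leaving out suffixed probe sets, and calls at 1.5-fold and 3-fold. Suffixed probe sets are those whose identifiers end in _x_at, _s_at or _a_at. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1, the last for cyclic loess.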

Results

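Transforming growth factor β (TGF-β) restrains T cell activation, and mice whose T cells lack its type II receptor develop fatal autoimmunity at a young age. The study examined the basis for the pathogenicity of receptor-deficient T cells that carry NK1.1, a surface marker of natural killer (NK) cells. RNA was profiled in CD8+ T cells sorted from mice with both copies of Tgfbr2 floxed and Cre recombinase under the Cd4 promoter (KO), 15 to 17 days old, as an NK1.1+ and an NK1.1− fraction, and in CD8+ T cells of littermates heterozygous for the floxed gene (control). The labels describe the control cells as NK1.1− in 2 places and as total CD8+ cells in another. Each of the 3 groups had 1 array, so every difference below is between single arrays and has no replicate check. Of 18193 genes, 9748 were measured on the NK1.1+ KO array, 9486 on the NK1.1− KO array and 9376 on the control array, with median values over all probe sets of 8.99, 8.24 and 8.18.

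The targeted gene was read by 3 probe sets. The brightest Tgfbr2 probe set gave values of 1808 in NK1.1+ KO, 1271 in NK1.1− KO and 2634 in control cells, 1.46-fold and 2.07-fold below control. The difference in NK1.1− KO cells was under 2-fold when all Tgfbr2 probe sets were averaged (log2 difference -0.47). Of the other Tgfbr2 probe sets, 1 was measured on the control array only, at 11.2, and 1 on none. The floxed exon is not given in the sources used here, so a probe set may lie outside the deleted part and then checks nothing. The probe set that the annotation assigns to both Klrb1b and Klrb1c, the latter encoding NK1.1, read 1618 in NK1.1+ KO, 52.7 in NK1.1− KO and 7.09 in control cells. The 5 probe sets of Cd8a, also a sort marker, disagreed. In the same order the brightest read 524, 1027 and 1786, others read 962, 815 and 962 and 21.3, 93.9 and 256, and the remaining 2 differed by at most 1.29-fold.

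The arrays differed in their technical controls. The ratio of 3′ to 5′ probe set values of Actb was 81.9 on the NK1.1+ KO array, 12.3 on the NK1.1− KO array and 6.02 on the control array, while that of Gapdh was 10.8, 26.7 and 17.8. In the same order the ratio was 35.3, 12.03 and 9.74 for the poly-A control lys, 18.5, 27.8 and 14.5 for dap, 3.98, 3.78 and 2.21 for phe and 18.1, 27.2 and 14.8 for thr. Log2 differences of probe sets of the same gene varied with a pooled SD of 0.85 for NK1.1+ KO against control, 0.42 for NK1.1− KO against control and 0.76 between the KO arrays, over 3679 genes with 2 or more measured probe sets. Hybridisation controls, which are added in a fixed amount, were 2.49-fold higher on the NK1.1+ KO array than on the control array and differed by 1.06-fold between the other arrays. Poly-A controls, added to the RNA, were 3.14-fold higher on the NK1.1+ KO array than on the control array, differed by 2.59-fold between NK1.1− KO and control and by 7.78-fold between the KO arrays.

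Receptor-deficient NK1.1− cells differed from control cells by a cytotoxic effector program, high proliferation transcripts and low transcripts of the naive state. Gzma, which encodes the killing protease granzyme A, read 19886 against 158 (126-fold higher), Gzmb, encoding granzyme B, 6098 against 120 (50.7-fold higher), and Gzmk at least 43.7-fold higher. Gzma was measured only by a suffixed probe set. Ifng, encoding interferon γ, was 24.3-fold higher, and Tbx21, encoding the effector transcription factor T-bet, 11.3-fold higher. The chemokine receptor gene Ccr7, which directs naive T cells to lymph nodes, read 67.1 against 1101 (16.4-fold lower). In all, 793 genes were called higher and 548 lower among 9818 measured on either array. Simulated unchanged arrays gave a mean of 328 higher and 327 lower calls.

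Of 20 measured cytotoxic granule and death ligand genes, 11 were called higher in NK1.1− KO than in control cells and 0 lower, with a median log2 difference of 1.45, at the percentile 100 of matched random lists. Effector transcription factors were called higher for 15 of 16 genes (median 1.70), among them Bhlhe40 (26.1-fold), Zeb2 (at least 6.91-fold) and Prdm1 (5.81-fold). NK cell receptor genes were called higher for 7 of 14, with 1 lower (median 0.94). Klrc1 was 8.03-fold, Klre1 6.85-fold and Slamf7 8.62-fold higher, and Klrb1f at least 12.99-fold higher, with 0.79 on the log2 scale by another Klrb1f probe set. Of 7 measured NK receptor adaptors, 2 were called higher and 0 lower, with Tyrobp at 52.6 against 21.6. Activation and memory markers were called higher for 10 of 21 and lower for 2 (median 0.89), with Lgals3 8.50-fold and S100a6 8.01-fold higher. Chemokine genes were called higher for 4 of 8 and lower for 0 (median 1.63), with Ccl5 at 12186 against 1119 and Ccl3 at least 17.9-fold higher. Of the 5 chemokine genes measured on the control array, 2 were higher. Chemokine receptors and homing molecules were called higher for 7 of 19 and lower for 2. Of the 14 of these measured on the control array, 5 were higher and 2 lower. The sphingosine-1-phosphate receptor gene S1pr5 was at least 111-fold higher, Cx3cr1 39.1-fold higher, and Itgae, which encodes the αE integrin of tissue-resident T cells, 9.97-fold lower. The remaining genes named among the largest differences above control were Baiap3 (24.8-fold), Dock5 (22.9-fold), Plek (17.2-fold), Smpdl3b (at least 35.3-fold), Esm1 (at least 26.6-fold) and Itgax (at least 18.1-fold). The smallest log2 difference among probe sets was 1.72 for Dock5 and 2.56 for Plek.

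Naive T cell genes were called lower in NK1.1− KO cells for 16 of 21 and higher for 0, with a median log2 difference of -1.75 at the percentile 0. Igfbp4 read 479 against 7032 (14.7-fold lower) and Dapl1 107 against 911 (8.51-fold lower). Of 9 measured genes known to be induced by TGF-β, 5 were called lower and 1 higher (median -1.02, percentile 0). Besides Itgae, the feedback inhibitors Pmepa1, Smad7 and Skil were 6.59-fold, 6.31-fold and 6.28-fold lower. Another probe set differed by only -0.14 on the log2 scale for Pmepa1 and -0.45 for Skil. Of 20 TGF-β pathway genes, 10 were called lower and 1 higher (median -1.02), among them Tgfbr3 (5.49-fold lower) and the receptor gene Acvr1b (5.04-fold lower). The lower genes include the targeted Tgfbr2 itself, and Smad7 and Skil, which also stand in the list of induced genes. The 2 lists are therefore not separate evidence. Regulatory T cell genes were called lower for 3 of 10 and higher for 1, with Gpr83 10.6-fold and Foxp3 2.92-fold lower. Other genes with large differences below control were St8sia6 (56.3-fold), Tdrp (15.4-fold), Als2cl (14.4-fold) and Ttc28 (10.1-fold), and, as lower bounds, Lypd6b (14.0-fold), Arhgap29 (12.4-fold), Adh1 (10.6-fold), Pdlim4 (8.71-fold) and Gpr15 (7.79-fold). Arhgap29 was under 2-fold when its probe sets were averaged. With a level at the 75th percentile of all values, the differences of Gpr15, Pdlim4, Foxp3, Klre1, Zeb2 and Tyrobp between NK1.1− KO and control cells were also under 2-fold.

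Proliferation genes were called higher in NK1.1− KO cells for 33 of 38 and lower for 0, with a median log2 difference of 2.04 at the percentile 100. Ccna2, encoding cyclin A2, read 437 against 49.3, Ube2c 182 against 21.9 and Plk1 213 against 27.8. Interferon-stimulated genes were called higher for 4 of 25 and lower for 0, apoptosis genes higher for 4 of 16 and lower for 2. Casp1 was 16.6-fold and Casp4 11.5-fold higher. Of 19 genes of common γ chain, interleukin-12 and interleukin-18 signalling, 4 were called higher and 1 lower, with Il18rap 9.84-fold higher. T cell cytokines were called higher for 2 of 9 and lower for 1, and inhibitory receptors higher for 4 of 11 and lower for 0. None of 25 oxidative phosphorylation genes, 21 ribosomal protein genes or 11 housekeeping genes was called. The ribosomal list had a median of -0.35 at the percentile 0.07. Of the T cell receptor complex and lineage genes, 1 of 20 was called higher and 2 lower, and of glycolysis genes 2 of 16 higher and 1 lower. Of markers of monocytes, macrophages and granulocytes, 0 of 10 were called. B cell markers were called lower for 3 of 12 and higher for 1 (median -0.59, percentile 0.14), erythroid markers lower for 2 of 6 and higher for 0 (median -0.67, percentile 0.76), and dendritic cell markers lower for 1 of 7 and higher for 1. The numbers of calls moved by over 1.5 times with a level at the 75th percentile of all values (493 higher, 310 lower), with an offset of 32 (473 and 237) and with the mean of all probe sets (524 and 351).

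Receptor-deficient NK1.1+ cells, set against control cells to ask what marks the NK1.1+ fraction of the mutants, also read high for effector genes and low for naive genes. Gzma read 31856 against 158 (202-fold higher), S1pr5 5741 against 10.05 (at least 556-fold higher) and Cx3cr1 2049 against 14.5 (141-fold higher). Igfbp4 read 12.6 against 7032 (559.9-fold lower, with log2 differences of -9.13 to -4.19 among its probe sets) and Ccr7 was at least 107-fold lower. Along with these, genes of the mononuclear phagocyte lineage stood among the largest differences, led by Csf1r, the receptor for macrophage colony-stimulating factor, at 7666 against 30.5 (251-fold higher, with log2 differences of 1.79 to 7.97 among its probe sets). S1pr5, Cx3cr1 and Zeb2 were also above control in NK1.1− KO cells, but which cells gave their signal on the NK1.1+ KO array was not tested. In all, 1011 genes were called higher and 2377 lower among 10328 measured on either array.

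NK cell receptor genes were called higher in NK1.1+ KO than in control cells for 11 of 16 and lower for 0, with a median log2 difference of 1.56 at the percentile 100. Klre1 read 1077 against 11.7 (92.0-fold higher), Klrc1, encoding NKG2A, 1274 against 27.9 (45.6-fold higher) and Cd244a, encoding 2B4, 705 against 48.1 (14.7-fold higher). Of 8 NK receptor adaptors, 5 were called higher and 0 lower. Tyrobp, encoding DAP12, was 54.8-fold higher and Fcer1g at least 25.2-fold higher, and both are also used by myeloid cells. Cytotoxic granule and death ligand genes were called higher for 10 of 19 and lower for 1 (median 1.05), with Fasl 17.1-fold, Gzmb 14.9-fold and Gzmk at least 26.1-fold higher. Effector transcription factors were called higher for 10 of 16 and lower for 2 (median 1.66), with Zeb2 at least 51.8-fold, Bhlhe40 24.04-fold, Tbx21 8.17-fold and Id2 6.73-fold higher. Chemokine genes were called higher for 7 of 9 and lower for 0 (median 3.47), with Ccl5 19.04-fold and Ccl6, a chemokine made by macrophages, 52.5-fold higher. Of the 5 chemokine genes measured on the control array, 4 were higher. Chemokine receptors and homing molecules were called higher for 8 of 19 and lower for 4. The 14 of these measured on the control array split evenly, with 4 higher and 4 lower. The other 5 were below the level on that array and could not be lower. T cell cytokines were called higher for 3 of 9 and lower for 1, with Ifng 18.8-fold higher. Activation and memory markers were called higher for 7 of 21 and lower for 6.

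Markers of monocytes, macrophages and granulocytes were called higher on the NK1.1+ KO array for 9 of 15 and lower for 0, with a median log2 difference of 1.25 at the percentile 100. Of the 15, 7 were below the level on the control array and could not be lower, and of the other 8, 5 were called higher. Lyz2, encoding lysozyme, was 22.9-fold and Adgre1, encoding the macrophage marker F4/80 and chosen after its value was seen, at least 6.45-fold higher. Lyz1 was 43.1-fold and C1qb at least 14.5-fold higher, and both were measured only by suffixed probe sets. Dendritic cell markers were called higher for 4 of 8 and lower for 2, with H2-Aa 4.67-fold higher (log2 differences of 0.47 to 2.22 among its probe sets). Of the 6 dendritic cell markers measured on the control array, 2 were higher and 2 lower. B cell markers were called higher for 5 of 13 and lower for 2 (median -0.24, percentile 33.2, and a median of 0.023 after quantile normalization), with Jchain, which joins secreted immunoglobulins, at 2282 against 15.9 (143-fold) and Ly86 18.7-fold higher. Fibroblast and endothelial markers were called higher for 2 of 4 and lower for 1, with Dcn at least 9.39-fold higher. Only 1 of these 4 was measured on the control array, and it was the lower one. Of hepatocyte markers, 1 of 2 was called higher, Hp by at least 6.66-fold, and with a level at the 75th percentile of all values Dcn and Hp were under 2-fold. Of erythroid markers, 2 of 6 were called lower and 0 higher. No platelet or megakaryocyte marker was measured on any array. Further genes far above control, by their brightest probe set, were Adgre4 (152-fold), Igk (92.4-fold), Klf4 (85.8-fold), Fpr2 (at least 80.4-fold), Tgfbi (at least 73.8-fold), Gab2 (at least 67.6-fold) and Smpdl3b (at least 58.7-fold). Igk and Gab2 were measured only by a suffixed probe set, and the smallest log2 difference among probe sets, with values below the level set to it, was 1.08 for Adgre4, 1.02 for Klf4 and 1.26 for Tgfbi.

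Naive T cell genes were called lower in NK1.1+ KO than in control cells for 17 of 21 and higher for 0, with a median log2 difference of -2.51 at the percentile 0. Dapl1 was 20.9-fold lower, and the 4 probe sets of Il6st ranged from -5.06 to -0.019 on the log2 scale. Regulatory T cell genes were called lower for 7 of 10 and higher for 1 (median -2.39), with Ctla4 18.8-fold, Ikzf4 17.1-fold and Foxp3 at least 9.40-fold lower, the last under 2-fold with a level at the 75th percentile. TGF-β pathway genes were called lower for 7 of 21 and higher for 2 (median -0.86), and genes known to be induced by TGF-β lower for 5 of 9 and higher for 2 (median -1.02, percentile 5.80). Of these genes Tgfbi differed most and was at least 73.8-fold higher. It read 762 in NK1.1+ KO, 15.4 in NK1.1− KO and 7.19 in control cells. Which cells gave the Tgfbi signal was not tested, and monocyte and macrophage genes were high on the NK1.1+ KO array. Itgae was 20.8-fold, Pmepa1 6.45-fold and Smad7 4.85-fold lower. Another probe set differed by only -0.14 on the log2 scale for Pmepa1 and -0.27 for Smad7. T cell receptor complex and lineage genes were called lower for 11 of 20 and higher for 1 (median -1.04, percentile 0.01), with Cd5 7.16-fold and Cd6 5.76-fold lower. Other genes far below control were St8sia6 (52.6-fold), Ift80 (46.1-fold), Nsg2 (24.7-fold) and Gart (19.5-fold, with log2 differences of -4.28 to -0.59 among its probe sets), and, as lower bounds, Tdrp (94.2-fold), Adcy6 (36.9-fold), Bag5 (34.3-fold) and Gpr83 (27.6-fold).

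Many lists of widely expressed genes were also low on the NK1.1+ KO array, on which the 3′ to 5′ ratio was the highest of the 3 arrays for Actb (81.9) and the lowest for Gapdh (10.8). Ribosomal protein genes were called lower for 10 of 21 (median -0.97), oxidative phosphorylation genes for 11 of 25 (median -0.71), glycolysis genes for 8 of 16 with 1 higher (median -1.07), and housekeeping genes for 5 of 11 (median -0.79). Rplp0 was 6.45-fold, Atp5b 9.54-fold and Pkm 6.01-fold lower. Interferon-stimulated genes were called lower for 10 of 25 and higher for 2 (median -0.73), proliferation genes lower for 15 of 38 and higher for 1 (median -0.76, percentile 1.56), and genes of common γ chain, interleukin-12 and interleukin-18 signalling lower for 7 of 18 and higher for 4. Of 16 apoptosis genes, 3 were called higher and 1 lower, of 21 immediate early and heat shock genes 4 higher and 3 lower, of 10 inhibitory receptors 2 higher and 2 lower, of 10 innate-like T cell genes 1 higher and 2 lower, and of 7 thymocyte genes 0 higher and 2 lower. The immediate early list had a median of 0.29, which was below 0 with the mean of all probe sets (-0.32) and without suffixed probe sets (-0.41).

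Lower calls outnumbered higher ones at 2-fold, but at 8-fold or more 168 genes were higher and 123 lower. The split of calls between NK1.1+ KO and control cells moved with the scaling: 29.8% of calls were higher as deposited and 40.7% after quantile normalization (1285 higher, 1870 lower), and the median log2 difference of genes measured on both arrays was -0.27 as deposited, -0.07 after quantile normalization and -0.40 after median centring. The counts moved by over 1.5 times with a level at the 75th percentile of all values (559 higher, 1475 lower), with an offset of 32 (582 and 1470) and, for higher calls, with the mean of all probe sets (536).

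Both KO subsets shared 332 genes called higher than control and 433 called lower. Independent lists of these sizes would share 76.2 and 124, and 100 simulated sets of unchanged arrays against a shared control shared at most 91 and 101. Both comparisons use the same control array, which cannot be split, so part of the excess may come from that array. The covariance of the log2 differences across genes was 0.49, against a mean of 0.14 in the simulated sets, and their correlation was 0.54, against a mean of 0.50 and a highest value of 0.52 in those sets, with genes that are not independent replicates. The simulated comparisons had fewer calls than the observed ones, a mean of 328 higher and 327 lower for NK1.1− KO, and their noise came from the NK1.1− KO and control arrays alone, so their overlap, covariance and correlation are not what unchanged lists of the observed length would give. Genes called higher in both included Gzma, Gzmb, Gzmk, Ifng, Fasl, Ccl5, Tbx21, S1pr5, Cx3cr1 and Klrg1, the last chosen after its values were seen and at 2615 in NK1.1+ KO, 2326 in NK1.1− KO and 397 in control cells. Genes called lower in both included Igfbp4, Ccr7, Dapl1, St8sia6, Itgae, Smad7 and Pmepa1.

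**Figure D1:**
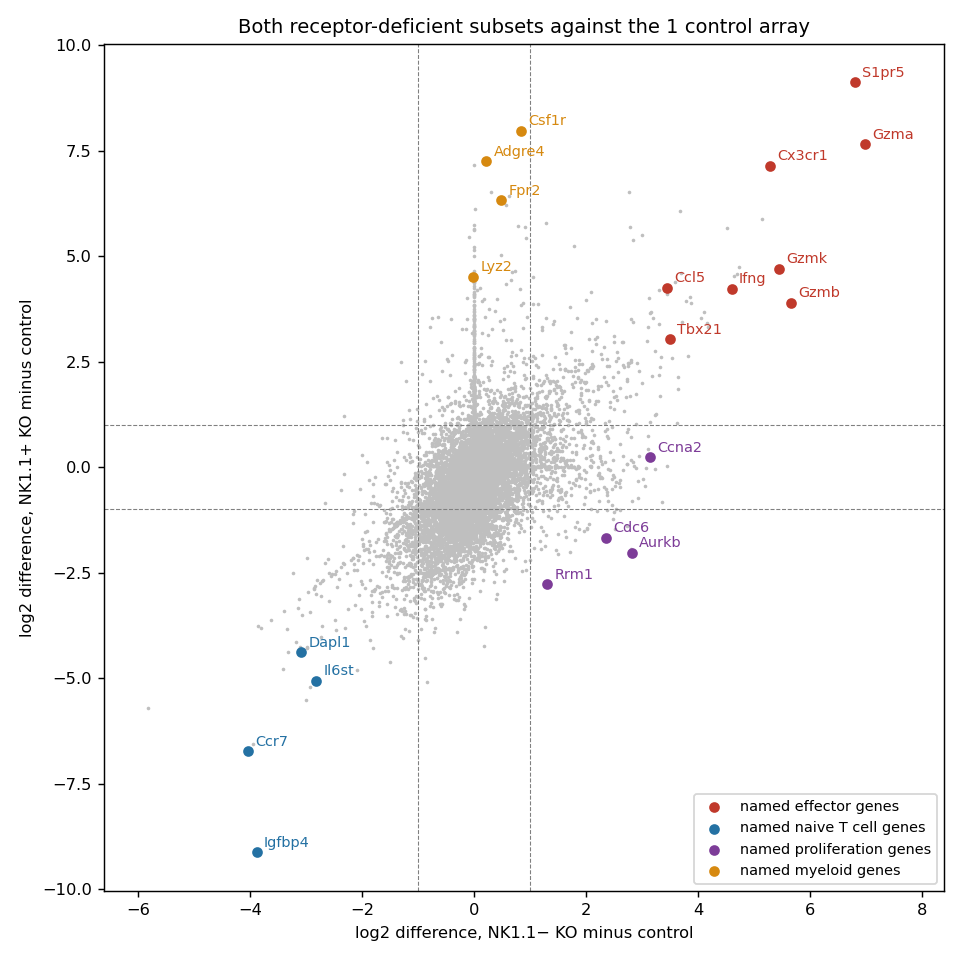
Log2 difference from the control array for NK1.1− KO cells (horizontal axis) and NK1.1+ KO cells (vertical axis), each point 1 of 10517 genes measured on any of the 3 arrays, with dashed lines at 2-fold. Effector genes such as Gzma (6.98 and 7.66) lie at the upper right, naive T cell genes such as Ccr7 (-4.04 and -6.74) at the lower left, Csf1r (0.84 and 7.97) lies along the vertical axis and Cdc6 (2.36 and -1.67) at the lower right.

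**Figure D2:**
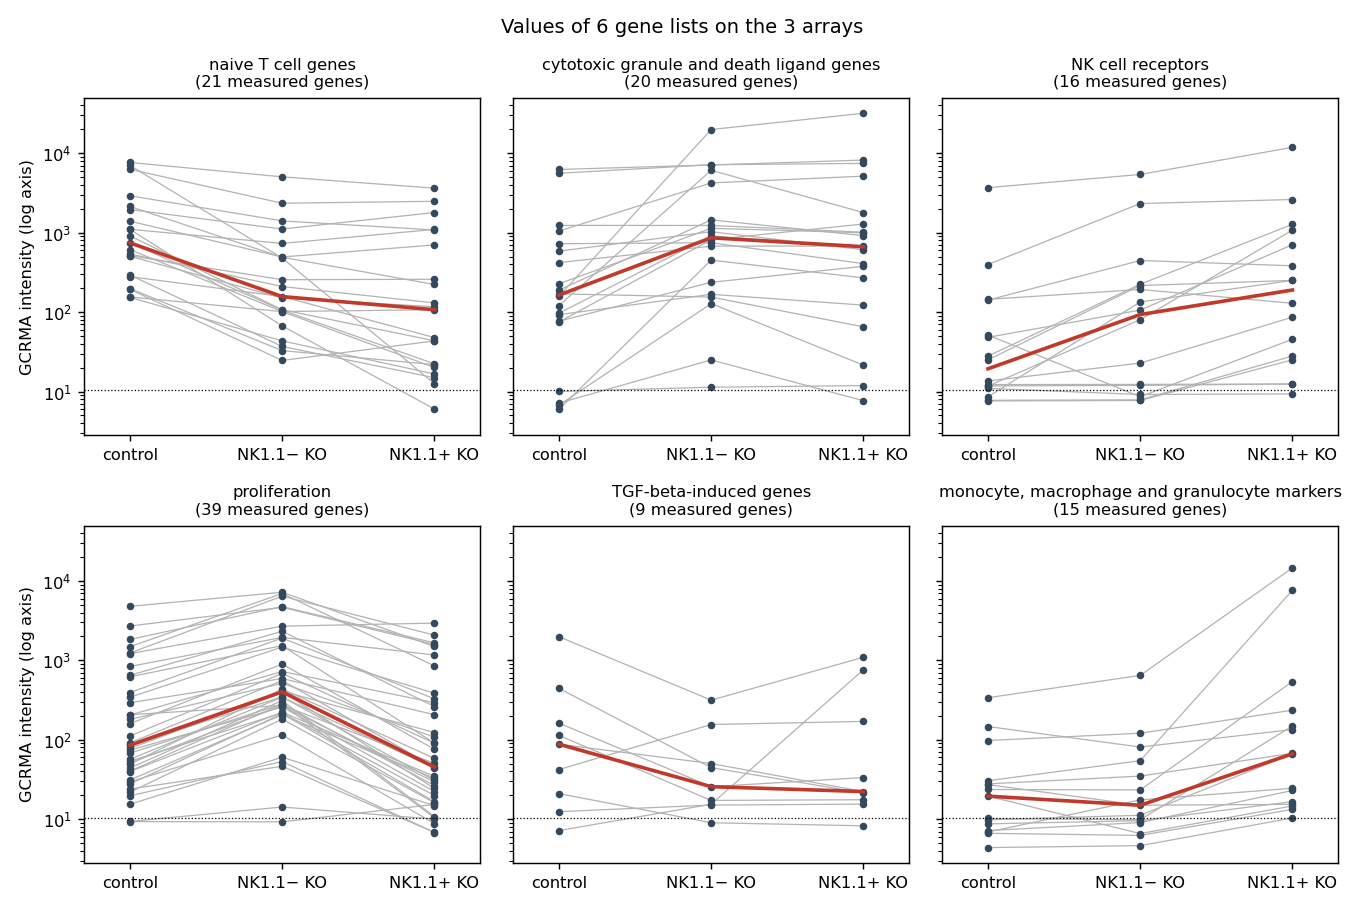
GCRMA intensity (log axis) of each measured gene of 6 lists on the control, NK1.1− KO and NK1.1+ KO arrays, 1 array each, with grey lines joining the values of a gene, the red line their median and the dotted line the measurement level of 10.3. Proliferation genes peak on the NK1.1− KO array, where 33 of 38 were called higher than control, and monocyte, macrophage and granulocyte markers are highest on the NK1.1+ KO array, where 9 of 15 were.

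The KO subsets were set against each other to ask what distinguishes NK1.1+ from NK1.1− receptor-deficient cells. NK cell receptor genes were called higher in NK1.1+ cells for 8 of 15 and lower for 0, with a median log2 difference of 1.14 at the percentile 100. Klre1 was 13.4-fold, Cd244a 6.66-fold and Klrc1 5.68-fold higher. NK receptor adaptors were called higher for 5 of 8 and lower for 1, with Fcer1g at least 25.2-fold and Tyrobp 22.5-fold higher. S1pr5 was 5.001-fold and Zeb2 7.49-fold higher. Whether T cells or other cells gave these differences was not tested, and monocyte and macrophage genes were high on the NK1.1+ KO array. The smallest log2 difference among probe sets was 0.94 for both Cd244a and Zeb2. In all, 660 genes were called higher and 2201 lower among 10320 measured on either array.

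Proliferation genes were called lower in NK1.1+ than in NK1.1− KO cells for 35 of 39 and higher for 0, with a median log2 difference of -2.68 at the percentile 0. The mitotic kinase gene Aurkb read 10.8 against 312 (28.9-fold lower), the thymidine kinase gene Tk1 10.4 against 282 (27.1-fold lower) and Rrm1, encoding a subunit of ribonucleotide reductase, 90.8 against 1531 (16.9-fold lower). Cdca5 was 17.4-fold, Cdc6 16.4-fold and Aurka at least 11.1-fold lower. Cdc6 was measured only by a suffixed probe set. Activation and memory markers were called lower for 9 of 21 and higher for 1 (median -0.83, percentile 0.47), with Il2rb 5.27-fold lower. Regulatory T cell genes were called lower for 7 of 10 and higher for 0, and the inhibitory receptor gene Ctla4 read 63.2 against 1344 (21.3-fold lower). Inhibitory receptors were called higher for 2 of 11 and lower for 4. Naive T cell genes were called lower for 9 of 21 and higher for 0 (median -0.59), at the percentile 18.1 of matched random lists.

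Cytotoxic granule and death ligand genes were called lower in NK1.1+ than in NK1.1− KO cells for 4 of 20 and higher for 0 (median -0.37, percentile 20.3), with Gzmb 3.41-fold lower. Effector transcription factors were called higher for 1 of 16 and lower for 4; their median of -0.16 was above 0 after quantile normalization (0.10) and cyclic loess (0.15). Chemokine genes were called higher for 3 of 9 and lower for 0, namely Ccl6 (30.5-fold), Cxcl9 (17.9-fold) and Ccl9 (8.01-fold), which myeloid cells also make and which stood beside the higher monocyte and macrophage markers of the same array. Chemokine receptors and homing molecules were called higher for 3 of 19 and lower for 4, with Cxcr5 5.90-fold and Cxcr3 4.37-fold lower. TGF-β pathway genes were called higher for 4 of 20 and lower for 2, with a median of 0.08 that was -0.041 after median centring. Genes known to be induced by TGF-β were called higher for 2 of 8 and lower for 2. Of the sex-linked genes, Xist read 4225 in NK1.1+ KO, 5490 in NK1.1− KO and 5154 in control cells, and 1 of 3 was called lower in NK1.1+ KO, the Y-linked Eif2s3y, at 25.7 in NK1.1− KO and below the level on the other arrays; it was under 2-fold with all probe sets averaged.

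Markers of monocytes, macrophages and granulocytes were called higher on the NK1.1+ than on the NK1.1− KO array for 6 of 15 and lower for 0 (median 0.95, percentile 100), and of the 9 measured on the NK1.1− KO array 4 were higher. B cell markers were called higher for 4 of 11 and lower for 0 (median 0.60, percentile 99.9), dendritic cell markers higher for 4 of 8 and lower for 2 (median 0.69, and -0.31 without suffixed probe sets), and fibroblast and endothelial markers higher for 2 of 3, none of which was measured on the NK1.1− KO array. By the brightest probe set, the largest differences were those of Jchain (143-fold), Csf1r (141-fold), Adgre4 (131-fold), Igk (74.4-fold), Vcam1 (69.0-fold), Fpr2 (57.3-fold), Klf4 (55.9-fold) and Tgfbi (49.4-fold), with, as lower bounds, Tnfaip2 (53.3-fold), Treml4 (49.95-fold), Clec4a3 (48.9-fold), Fcgr4 (37.3-fold) and Klkb1 (35.7-fold). With values below the level set to it, the smallest log2 difference among probe sets was 0.15 for Vcam1, 1.08 for Adgre4, 1.02 for Klf4, 1.26 for Tgfbi and 1.79 for Csf1r. Tnfaip2, like Igk, was measured only by a suffixed probe set. Below NK1.1− KO cells lay Igfbp4 (38.1-fold, with log2 differences of -5.25 to -0.49 among its probe sets) and Lrr1 (18.2-fold, measured only by such a probe set) and, as lower bounds, Bag5 (19.2-fold), Wdr74 (12.4-fold), Fkbp2 (11.4-fold) and Coq7 (10.7-fold).

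T cell receptor complex and lineage genes were called lower on the NK1.1+ than on the NK1.1− KO array for 9 of 20 (median -0.89), oxidative phosphorylation genes for 11 of 25 (median -0.81), glycolysis genes for 8 of 16 (median -0.96), interferon-stimulated genes for 7 of 24 (median -0.76), ribosomal protein genes for 4 of 21 (median -0.66) and housekeeping genes for 4 of 11 (median -0.73), with 0 higher in each of these lists. Of all genes, 530 were called higher in NK1.1+ KO than on both other arrays and 1530 lower. At 8-fold or more, 109 genes were higher and 67 lower than in NK1.1− KO cells. Of calls between the KO arrays, 23.1% were higher as deposited, 36.3% after quantile normalization (920 higher, 1613 lower) and 36.4% after cyclic loess (908 and 1587), and the median log2 difference of genes measured on both arrays was -0.33 as deposited and -0.11 after quantile normalization. The counts moved by over 1.5 times with a level at the 75th percentile (323 higher, 1287 lower), with an offset of 32 (360 and 1188) and, for higher calls, with the mean of all probe sets (310).

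**Figure D3:**
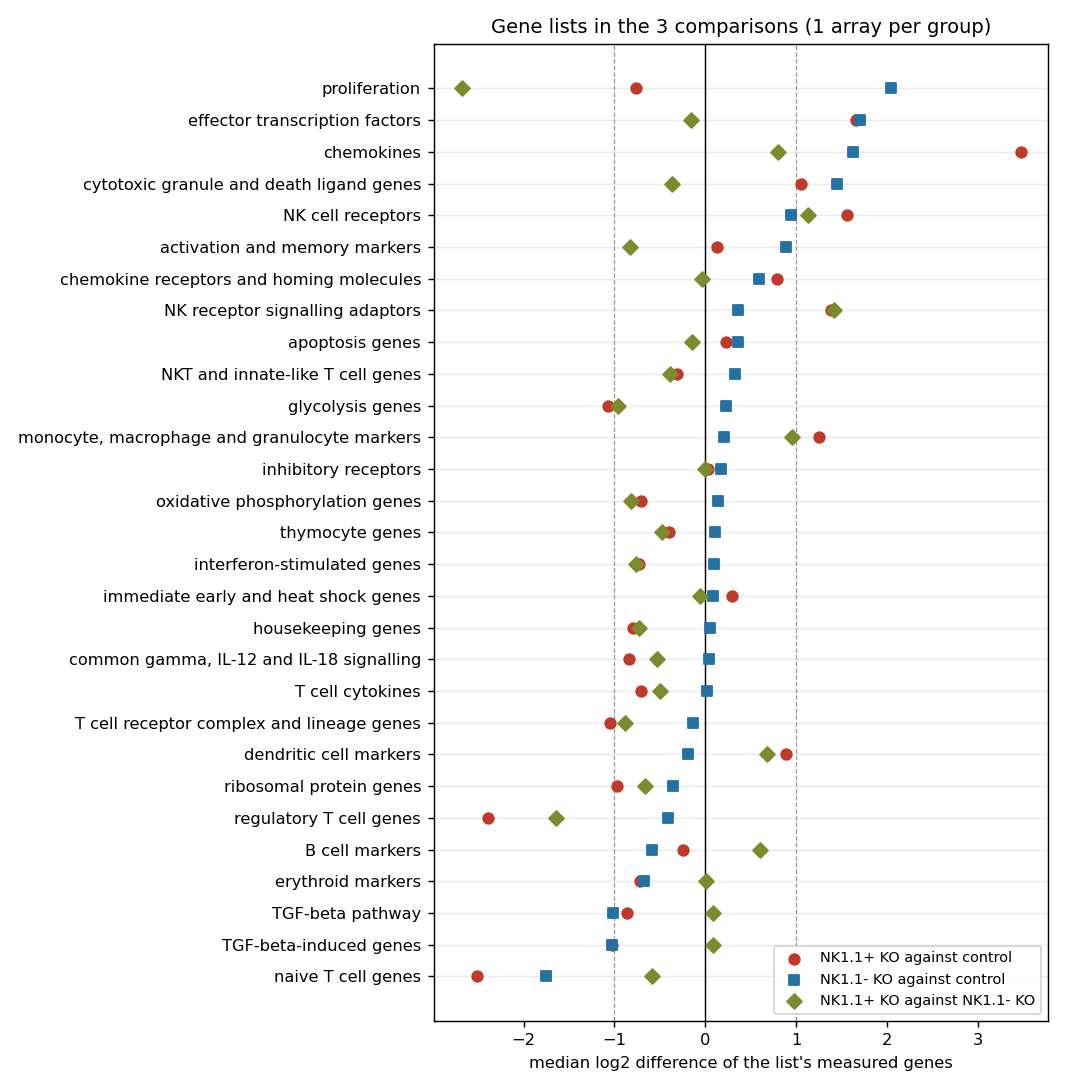
Median log2 difference of the measured genes of each of 29 lists (horizontal axis) in the 3 comparisons, with 1 array per group and dashed lines at 2-fold. Proliferation genes lie at 2.04 for NK1.1− KO against control, -0.76 for NK1.1+ KO against control and -2.68 between the KO arrays, and naive T cell genes lie at -1.75, -2.51 and -0.59.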

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

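The tests of a general rise of dim genes, of a general loss of signal and of dilution by other cells were chosen after their results had been seen; the other tests were fixed before.

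Differences from the control array went in opposite directions on the 2 KO arrays for 44 genes called lower in NK1.1+ KO and higher in NK1.1− KO than control, and for 9 genes called higher in NK1.1+ KO and lower in NK1.1− KO. The difference was not tested, because each group had 1 array, and with no NK1.1+ control array the values of NK1.1+ KO cells cannot be assigned to receptor loss. Of the 44, 12 belong to the proliferation list, whose median log2 difference from control was -0.76 in NK1.1+ KO and 2.04 in NK1.1− KO. In NK1.1+ KO against control, housekeeping (-0.79), ribosomal protein (-0.97), oxidative phosphorylation (-0.71) and glycolysis genes (-1.07) were about as low as proliferation genes, so the low side of that list is not particular to it. Among the named genes the values in NK1.1+ and NK1.1− KO were -2.03 and 2.82 for Aurkb, -1.95 and 2.81 for Tk1, -1.52 and 1.96 for Aurka, -1.67 and 2.36 for Cdc6, -1.39 and 2.73 for Cdca5, and -2.77 and 1.30 for Rrm1, for which another probe set gave -0.076 in NK1.1− KO. The NK1.1+ KO differences of Aurkb and Tk1 were 0 with a level at the 75th percentile of all values and -0.83 and -0.77 with an offset of 32.

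For the difference of proliferation genes between the KO arrays, a general loss of signal on the NK1.1+ KO array would leave the list inside the range of matched random lists, but its median against NK1.1− KO lay at the percentile 0 of them. Dilution of T cells by other cells would lower proliferation and T cell lineage genes alike. The proliferation median was nevertheless lower by -1.80 on the log2 scale (95% bootstrap interval over genes -2.48 to -1.16). That interval takes genes as independent, which they are not, and holds no spread between mice or arrays. The values show that proliferation genes fell further than matched genes and than lineage genes. They decide neither cause: the first restates the pattern, and the second assumes that the other cells lack the lineage transcripts, which was not examined. A lower rate of division of the NK1.1+ cells may account for the pattern and was not tested against shortened RNA on that array, which stays open for these genes.

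More genes were called lower than higher at 2-fold on the NK1.1+ KO array, while at 8-fold or more 168 were higher and 123 lower than on the control array. Uneven scaling may account for part of this and, by its test as written beforehand, not for the whole, since 70.2% of calls against control were lower as deposited and 61.5% after cyclic loess, although the bound of 60% was passed only narrowly and quantile normalization gave 59.3%. The B1 repeat control probe set, which the comparisons did not use, was higher by 2.06 on the log2 scale than on the control array. The B2 repeat control rose less, at 57242 against 38552 on the control array. Its 57242 was the highest value on the NK1.1+ KO array, and whether the top of the scale limited its rise was not examined. Measured probe sets without a gene symbol, 3598 in number, were shifted up by 0.58 relative to single-gene probe sets of like mean value. For NK1.1− KO against control that shift was -0.017. Unspliced RNA or genomic DNA in the sample could give the rise of B1 and of the probe sets without a symbol. Shortened RNA was expected to leave lower calls borne out by every probe set of a gene less often than higher calls. Of lower calls 27.4% and of higher calls 20.9% were borne out, with a standard error of 2.44 over genes taken as independent. The difference of -6.51 percentage points counts against shortened RNA by the rule written beforehand. After this value was seen it was recognized that unspliced RNA could itself make higher calls disagree between probe sets, so shortened RNA is not excluded, and the 3′ to 5′ ratios do not settle it: on this array those of Actb and of the poly-A controls lys, dap, phe and thr were higher than on the control array and that of Gapdh lower, while against the NK1.1− KO array, where 76.9% of calls were lower too, dap (18.5 against 27.8), thr (18.1 against 27.2) and Gapdh (10.8 against 26.7) were lower and Actb (81.9 against 12.3), lys (35.3 against 12.03) and phe (3.98 against 3.78) higher; a broad biological difference of NK1.1+ cells also stays open, as untested.

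Monocyte and macrophage genes were high on the NK1.1+ KO array, and a second list of 35 monocyte genes, none of which is in another list and 16 of which were measured on the control array too, was called higher than on the NK1.1− KO array for 20 of 32 measured genes (62.5%) and lower for 1, as monocytes or macrophages among the sorted cells would give. Of the 32, 17 were below the level on the NK1.1− KO array and could not be lower, and of the other 15, 8 were higher. In a list of 12 red pulp macrophage genes, 6 of 7 measured genes were called higher and 0 lower (median 1.59, percentile 99.9). Only 2 of the 7 were measured on the NK1.1− KO array (1 of them higher), so the other 5 could not be lower. With 5 of the 12 measured on no array, this list adds little by itself. Among abundant genes of that lineage Csf1r read 7666, Lyz2 541 and Mpeg1 856, while Cd14, C5ar1 and Vcan were below the level. The low genes decide nothing about such cells, because subsets of monocytes were not told apart. Of the 35 genes of the second list, 3 were below the level on all 3 arrays. The first list's percentile of 100 among matched random lists shows a rise beyond genes of like mean value. That value restates the pattern, and 6 of the list's 15 measured genes were below the level on the NK1.1− KO array and could not be lower. A general rise of dim genes is therefore not excluded. A plasma cell list had 22.2% of 9 measured genes higher, namely Xbp1 (1675.5 against 731) and Mzb1 (37.6 against 11.5), 3 lower and a median of -0.017. By its rule this counted against plasma cells, and 4 of its 14 genes were below the level on all 3 arrays. It decides nothing about plasma cells, though, because most of the measured genes were well measured on the NK1.1− KO array too (Edem1 at 615) and Jchain was high. The plasma cell list does not bear on monocyte genes. The cells were sorted for CD8 and NK1.1, but how many other cells remained was not examined here. Transcription of these genes by the NK1.1+ T cells themselves, which the design names as a separate fraction, stays open as untested.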

How the results depend on the processing

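Of the counts of calls under an alternative, 66 stayed within 1.5 times the reported count and 52 moved. Median centring, quantile normalization, cyclic loess, a level at the median of all values, no level, and leaving out suffixed probe sets moved none of the 10 counts. The 2 alternatives that asked every probe set of a gene to pass, and that left the NK1.1+ KO array out of the choice of probe sets and level, were chosen after the data were seen; the second gave 813 higher and 561 lower for NK1.1− KO against control. No paired analysis was possible because each group has 1 array, and for the same reason no array could be left out of its own comparisons. Where the construction of an alternative does not show why a count moved, the cause was not tested.

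Counts are given as higher then lower for NK1.1+ KO against control, NK1.1− KO against control, NK1.1+ against NK1.1− KO, both KO subsets against control, and NK1.1+ KO set apart from both other arrays. A level at the 75th percentile of all values (54.0) gave 559 and 1475, 493 and 310, 323 and 1287, 201 and 241, and 238 and 842. An offset of 32 gave 582 and 1470, 473 and 237, 360 and 1188, 188 and 184, and 280 and 740. Calls at 1.5-fold numbered 1757 and 3652, 1593 and 1470, 1310 and 3721, 672 and 1183, and 1038 and 2710, and calls at 3-fold 528 and 1164, 368 and 142, 344 and 886, 151 and 115, and 293 and 549. The mean of all probe sets moved the higher counts to 536, 524, 310, 200 and 263 and the lower count of NK1.1− KO against control to 351. Asking every 1 of 2 or more measured probe sets to pass left 90 and 255, 134 and 65, and 40 and 201 in the first 3 comparisons, with only genes that have several measured probe sets entering.

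Over all alternatives, list medians changed sign 52 times, 18 of them under the 3 other scalings, mostly where the reported median lay near 0. In 4 of the 52 the reported median stood apart from matched random lists. The TGF-β pathway list between the KO arrays came to -0.041 with median centring, immediate early and heat shock genes in NK1.1+ KO against control to -0.32 with the mean of all probe sets and -0.41 without suffixed probe sets, and dendritic cell markers between the KO arrays to -0.31 without those probe sets. Besides these 4, 67 list medians moved by over 1.5-fold, some of them with a change of sign. Values of named genes changed sign 4 times, in 1 of them for a difference of 2-fold or more, Itgae between the KO arrays, at 0.016 without those probe sets, and 599 others moved by over 1.5-fold. Of 337 named gene differences of 2-fold or more, 127 were under 2-fold with at least 1 alternative, which includes genes no longer measured under it.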

Other observations

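Some genes stood at nearly the same level in both receptor-deficient fractions and far from control; those named here were chosen after their values were seen and are given by their brightest probe set. Esm1 read 275 in both KO fractions against 10.3 in control cells, Alcam, an adhesion molecule of activated T cells, 331 and 327 against 22.4, Hip1 169 and 149 against 6.41, and Abcb1a, encoding a drug efflux pump, 394 and 317 against 50.8, with the NK1.1+ KO value first. Other probe sets differed less, down to 0.17 on the log2 scale for Alcam in NK1.1+ KO and 0.57 for Hip1 in NK1.1− KO. Pmaip1, encoding the BH3-only protein NOXA, read 358 and 337 against 34.1. In the other direction, Atp1b1, a subunit of the sodium pump, read 394 and 449 against 3181, the transcription factor gene Sox4 107 and 102 against 612, Inpp4b 41.8 and 42.2 against 248, Cxxc5 29.96 and 29.4 against 191 and the cannabinoid receptor gene Cnr2 31.1 and 30.7 against 220.5.

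Genes of the regulatory T cell list were measured on the control array, with Foxp3 at 97.1, Ikzf4 at 298 and Ctla4 at 1189. Foxp3 read 33.3 on the NK1.1− KO array and was below the level on the NK1.1+ KO array. Immunoglobulin M heavy chain (Ighm) read 10744, 771 and 1904 on the NK1.1+ KO, NK1.1− KO and control arrays by its brightest probe set, and its call ended with the mean of all probe sets and without suffixed probe sets.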
